A study of Mus musculus with 44 samples.

How the data were processed

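The libraries were chromatin immunoprecipitation and input libraries of mouse haematopoietic progenitor cells, in a series that also names MNase sequencing. Per the labels, cultured IdHP cells were fixed with formaldehyde and their sheared chromatin was precipitated with antibodies to FLAG, RING1B, SUZ12, H3K27me3, H3K27ac and other targets. The labels assign 44 libraries to 23 groups by cell type, genotype and antibody. A deposited text names the 2 libraries behind each peak list: FLAG in Pcgf1 -/- IdHP cells with FLAG-PCGF1, RING1B in Pcgf1 fl/fl IdHP cells, and H3K27me3 in Pcgf1 fl/fl IdHP cells. The other 38 libraries have no values here.

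Per the submitters' processing notes, Bowtie2, SAMtools 1.6.0 and Picard were used and the builds were mm9 and dm3, with no role given for either build; the mouse positions are read as mm9. The peak caller, its threshold and its control library are not given in the sources used here. Nor is it stated whether reads were pooled before calling or lists merged after it. The PCGF1 and RING1B lists are in the broadPeak layout. In that layout the deposited fold enrichment is the mean ratio over the caller's background, and the deposited -log10 q is the significance of the peak. The deposited score was 10 times the -log10 q, rounded down, in every peak, and adds nothing to it. Per the file headers, the H3K27me3 list gives a height (the highest signal in a region), a total signal, a width above the cutoff and a log p of the height, read here as -log10 p. The scale of that signal is not stated, its lowest height was 40, and positions run in steps of 10 bp. It has no fold, so height ranked its regions. These are the authors' own values per peak, and they were used to describe, rank or filter peaks within a list. Read depth is unknown from these lists, and a low-depth library gives fewer and shorter peaks, so the numbers of peaks in different lists do not measure how much of each protein was bound. The FLAG libraries came from other cells than the RING1B and H3K27me3 libraries, so overlap sets sites side by side across 2 cell populations.

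Peaks were compared by overlap of at least 1 bp. For each of 3 pairs of lists, each query peak was placed at random 1000 times within its own chromosome, between the first and last base covered by any list, with its width kept (a permutation of positions), and the observed share was divided by the mean random share. Placement spans unsequenced gaps and unmappable sequence, which lowers the random share. It does not adjust for sequence that both lists may favour, such as promoters. For 4 comparisons of peaks with and without another peak, the difference in share or in median log2 fold was set against 10000 random sets of the same size with the same number of peaks in each of 10 width deciles; the peak labels were thus permuted within width deciles, and the excess is the observed difference minus the mean of those sets. A threshold of 0.05 was used for each of the 7 tests. The report gives unadjusted p values; adjusted over the 7 tests by the Benjamini-Hochberg method, they were 0.00117 for the 3 overlaps, 0.0034 for PCGF1 fold and H3K27me3, and 0.000467 for the others. Beside the binomial intervals of shares of peaks, ratios of peak counts have exact binomial or exact conditional intervals, observed over expected numbers exact Poisson intervals, medians intervals from 1000 bootstrap samples, and the covered share of X an interval from 1000 resamplings of its blocks of 1 Mb. Peaks are not replicates, and neighbouring peaks are not independent, so each p describes these lists and not the spread between cultures or animals. Positions of PCGF1 and RING1B peaks are 1-based, and those of H3K27me3 regions are as the list gives them. The rule for naming sites, fixed before the data were examined, took the 10 peaks of each list with the highest fold, or height for H3K27me3; regions with other features were named after their values were seen.

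Genes were not assigned. The gene table used with this work belongs to GRCm38.p6, another build than mm9, so promoter shares, co-occupancy of promoters and the 14 gene lists fixed before the data were examined were not tested. The comparison of Pcgf1 -/- with fl/fl cells was not analysed here, since no values per library were used.

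Alternatives fixed before the data were examined were 50% of the query peak covered, peaks within 1 kb, the stronger 50% of both lists, a -log10 q or p of at least 5, rotation of a list along each chromosome, no matching on width, and autosomes alone. Alternatives chosen after seeing the data were random shifts of 10 to 50 kb, lists without chromosome 8, lists without H3K27me3 regions of height 400 or more and the peaks on them, the taller 50% of H3K27me3 regions, the patterns of the closing section without a dense block on chromosome 8, and the PCGF1 peaks of -log10 q of at least 5 against the whole RING1B list. The procedures were tested on simulated data for the overlap of PCGF1 with RING1B and for the RING1B fold with against without PCGF1. With 32.0% and 70.6% of 2552 simulated PCGF1 peaks planted in RING1B peaks, 31.8% and 70.8% were recovered, and with none planted 0.0495%. Over 24987 simulated RING1B peaks with a width trend, a planted log2 shift of 0.1 came back as 0.12 and a shift of 0 as -0.0017. Simulated peaks were placed independently of each other and their folds had independent noise, while neighbouring real peaks are not independent. The simulations thus check the calculation and not the effect of clustering. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.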

Results

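Chromatin immunoprecipitation and sequencing were carried out on mouse haematopoietic progenitor cells with and without PCGF1, a subunit that defines a variant form of Polycomb repressive complex 1. The labels describe 44 libraries in 23 groups. Of these, 36 came from IdHP cells, progenitors kept in culture on TSt4 stroma with IL7, SCF and Flt3L for 15 to 18 passages, and 8 from LSK cells, a bone marrow fraction rich in stem cells and early progenitors, of mice aged 8 to 10 weeks. There were 21 groups of 2 libraries and 2 groups of 1 library. The 3 peak lists analysed here each cover a pair of IdHP libraries: PCGF1, mapped by its FLAG tag in Pcgf1 -/- cells given FLAG-PCGF1; RING1B, the ubiquitin ligase subunit of the complex, in Pcgf1 fl/fl cells; and H3K27me3, the histone mark written by Polycomb repressive complex 2, in Pcgf1 fl/fl cells. Values for the other 38 libraries were not analysed here, so the lists describe where the proteins and the mark lay and hold no comparison of Pcgf1 -/- with fl/fl cells. No value has a replicate error, because each list stands for both of its libraries, and the read depth is unknown. Intervals given with shares of peaks are exact 95% binomial (Clopper-Pearson) intervals and cover counting error only.

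The PCGF1 list was short and made of narrow peaks, the RING1B list was about 10 times as long, and the H3K27me3 list covered wide stretches of the genome; with unknown depth these sizes do not measure how much was bound. The PCGF1 list held 2569 peaks with a median width of 224 bp (interquartile range 128 to 496), together 1.08 Mb. The RING1B list held 24987 peaks with a median width of 744 bp (402 to 1547) and covered 39.7 Mb. The H3K27me3 list held 135391 regions with a median width of 1840 bp (1210 to 3520) and covered 484.0 Mb, which was 18.3% of the span of the chromosomes between the first and last listed base. The authors' fold enrichment had a median of 4.79 over PCGF1 peaks and 3.22 over RING1B peaks, each relative to its own background, so the 2 medians are not comparable. Most PCGF1 peaks lay near the calling threshold: their median -log10 q was 1.97, and 64 of 2569 reached 5. Most RING1B peaks did so too, with a median of 2.28 and 2488 of 24987 that reached 5.

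The first comparison asked how much of PCGF1 binding fell on RING1B, its partner in the complex. PCGF1 sites were mostly RING1B sites: 1935 of the 2569 PCGF1 peaks (75.3%, interval 73.6 to 77.0) shared at least 1 bp with a RING1B peak. In the other direction, 1461 RING1B peaks (5.85%, 5.56 to 6.15) held a PCGF1 peak, a share that the lengths of the lists would hold to 10.3% even if each PCGF1 peak lay in a RING1B peak of its own. PCGF1 peaks on RING1B were wider than those off it (median 263 against 165 bp) and had a slightly higher median fold (4.82 against 4.71). The share on RING1B went from 65.8% (62.0 to 69.5) in the 25% of PCGF1 peaks with the lowest -log10 q to 84.1% (81.1 to 86.9) in the 25% with the highest. With both lists limited to their stronger 50% the share was 65.1%, and with both limited to a -log10 q of at least 5 it was 21.9% (14 of 64), while 56 of those 64 PCGF1 peaks (87.5%, 76.8 to 94.4) lay on a peak of the whole RING1B list. Those 64 peaks had lower folds than the whole list, with medians of 4.34 on H3K27me3 and 3.90 off it, against 4.79. A high -log10 q at a low fold can come from high local background, which was not tested for them. Random placement of the PCGF1 peaks within their chromosomes put 2.11% of them on RING1B (central 95% of placements 1.56 to 2.69), so the observed overlap was 35.7-fold higher (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The ratio was 22.1 when peaks within 1 kb of each other counted as overlapping, and 10.8 when each peak was instead moved 10 to 50 kb from its own position, a setting chosen after seeing the data. None of these ratios adjusts for a preference of both lists for promoters, since co-occupancy of promoters was not tested.

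**Figure D1:**
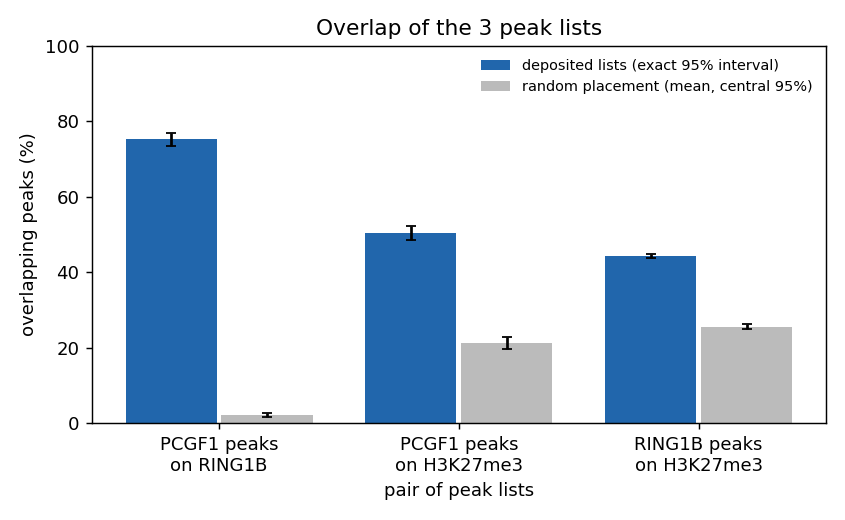
Share of peaks (y axis, percent) that share at least 1 bp with a peak of another list, for the 3 pairs of lists (x axis). Blue bars are the deposited lists with exact 95% intervals and grey bars the mean and central 95% of 1000 random placements; PCGF1 on RING1B stands at 75.3% against 2.11%, PCGF1 on H3K27me3 at 50.4% against 21.2%, and RING1B on H3K27me3 at 44.3% against 25.6%.

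PCGF1 also overlapped H3K27me3 more often than placement at random gave, though by far less than RING1B. Of the PCGF1 peaks, 1295 (50.4%, 48.5 to 52.4) lay on an H3K27me3 region. Taking both partners together, 1007 PCGF1 peaks (39.2%) lay on RING1B and H3K27me3, 928 (36.1%) on RING1B without H3K27me3, 288 (11.2%) on H3K27me3 without RING1B, and 346 (13.5%) on neither. Peaks on both were the widest, with a median of 378 bp, and peaks on neither the shortest, with a median of 157.5 bp. Random placement gave 21.2% on H3K27me3 (19.6 to 22.7), a 2.38-fold difference (one-sided permutation p = 0.001, the smallest possible). The ratio was 3.59 with both lists limited to their stronger 50% and 1.35 against positions 10 to 50 kb away, where 37.2% of moved PCGF1 peaks fell on H3K27me3.

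Among RING1B peaks, 11081 (44.3%, 43.7 to 45.0) lay on H3K27me3 and 13906 (55.7%) did not. RING1B peaks on H3K27me3 were about 2 times as wide as the others, with medians of 1170 and 594.5 bp. The share on H3K27me3 went from 29.1% (28.2 to 30.1) in RING1B peaks of up to 500 bp to 96.8% (94.7 to 98.2) in the 464 peaks wider than 10000 bp. Random placement gave 25.6% (25.1 to 26.2), a ratio of 1.73 (one-sided permutation p = 0.001, the smallest possible). Against positions 10 to 50 kb away, where 40.6% of moved peaks fell on H3K27me3, the ratio was 1.09.

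RING1B peaks that held PCGF1 differed from the rest in width first. Their median width was 2054 bp, against 712 bp for RING1B peaks without PCGF1. PCGF1 was found in 1.63% (1.37 to 1.93) of RING1B peaks of up to 500 bp, 7.32% (6.60 to 8.09) of those of 1000 to 2000 bp and 25.6% (21.7 to 29.9) of those wider than 10000 bp. A peak with more bases has more chance of holding another peak, so RING1B peaks with and without PCGF1 were compared against random sets of the same size drawn within the same width deciles.

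H3K27me3 lay on 56.8% of RING1B peaks with PCGF1 and on 43.6% of those without, a difference of 13.2 percentage points. Sets matched on width differed by 17.9 points (15.7 to 20.1), so at a given width RING1B peaks with PCGF1 were on H3K27me3 less often, by -4.68 points (two-sided permutation p = 0.0002, the smallest that 10000 sets can give). The direction was not uniform over widths. Between 1000 and 2000 bp, 34.3% (29.3 to 39.5) of RING1B peaks with PCGF1 lay on H3K27me3, against 47.3% (45.8 to 48.8) of those without, and between 2000 and 5000 bp 63.8% (59.1 to 68.3) against 74.0% (72.4 to 75.6). Up to 500 bp the order was the other way, 44.4% (35.9 to 53.2) against 28.9% (27.9 to 29.9). Above 10000 bp, 119 of the 119 RING1B peaks with PCGF1 lay on H3K27me3, against 95.7% (92.9 to 97.5) of those without. The matched difference was -4.94 points (two-sided permutation p = 0.0002) with peaks within 1 kb, but 1.69 points (permutation p = 0.195) when 50% of a peak had to be covered, -2.09 points (permutation p = 0.0800) with the taller 50% of H3K27me3 regions, and 13.2 points without matching on width. With both lists limited to -log10 q of at least 5 it was 42.1 points, from 14 RING1B peaks with a PCGF1 peak of that limit. RING1B peaks whose PCGF1 peaks fell below the limit were counted on the other side.

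**Figure D2:**
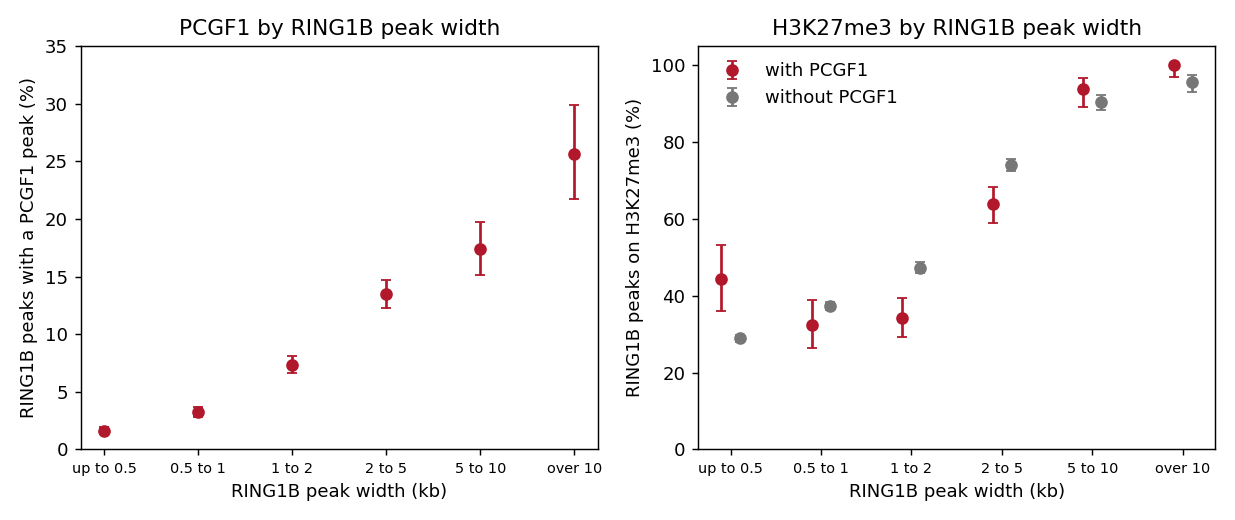
RING1B peaks by width class in kb (x axes). The left panel gives the percentage that hold a PCGF1 peak, from 1.63% to 25.6%, and the right panel the percentage on H3K27me3 for RING1B peaks with PCGF1 (red) and without (grey), with red below grey at 34.3% against 47.3% for 1 to 2 kb; points are shares and bars exact 95% intervals.

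RING1B peaks with PCGF1 had a higher median fold, though not at every width. Their median fold was 3.55, against 3.21 without PCGF1, a log2 difference of 0.14 where width-matched sets gave 0.08 (0.06 to 0.09). The excess of 0.07 had a two-sided permutation p of 0.0002, the smallest possible. Differences in width within a decile were not removed, and the widest decile runs up to 65223 bp. Since the PCGF1 share and the RING1B fold both rose with width among wide peaks, this can add to the excess. Among RING1B peaks wider than 10000 bp the medians were 5.89 with PCGF1 and 4.14 without, and between 500 and 1000 bp 3.20 and 3.13. Up to 500 bp, the class with the most RING1B peaks, the order was the reverse, 2.99 in 135 peaks with PCGF1 against 3.12 in 8126 without. PCGF1 was present in 2.69% (2.30 to 3.12) of the 25% of RING1B peaks with the lowest fold and in 11.5% (10.8 to 12.4) of the 25% with the highest. These groups were not matched on width, and their median widths were 515 bp and 1230 bp. With both lists limited to -log10 q of at least 5 the order turned, with an excess of -0.74. The 14 RING1B peaks with a PCGF1 peak of that limit had a median fold of 2.80, against 4.74 in the others. RING1B peaks whose PCGF1 peaks fell below the limit were counted among those others, which are thus not a group without PCGF1. Without width matching the excess was 0.14.

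H3K27me3 went with a slightly lower RING1B fold at a given width. The median RING1B fold was 3.20 on H3K27me3 and 3.25 off it, a log2 difference of -0.02 where width-matched sets gave 0.06 (0.05 to 0.06), so the excess was -0.08 (two-sided permutation p = 0.0002, the smallest possible). Among the 25% of RING1B peaks with the highest fold, 38.8% (37.6 to 40) lay on H3K27me3, against 45.8% (44.5 to 47.0) among the 25% with the lowest. The share did not fall steadily: it was 48.2% in the 25% next above the lowest and 44.7% in the 25% next below the highest. For PCGF1 the direction was the opposite and the size small: the median fold was 4.88 on H3K27me3 and 4.73 off it, a log2 difference of 0.043 against 0.031 (0.022 to 0.039) in matched sets, an excess of 0.012 (two-sided permutation p = 0.0034). With chromosome 8 left out, a setting chosen after seeing the data, the PCGF1 excess was 0.010 (two-sided permutation p = 0.032). Without width matching the RING1B excess was -0.022 and the PCGF1 excess 0.043. With -log10 q of at least 5 neither passed the test, at 0.0065 for RING1B (permutation p = 0.417) and 0.045 for PCGF1 (permutation p = 0.677).

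Single sites are given by position in build mm9. The highest PCGF1 fold, 7.40, was at chromosome 17, 26249971 to 26251298, on a RING1B peak of fold 2.91 and an H3K27me3 region. Of the 10 PCGF1 peaks with the highest fold, 8 lay on RING1B and 5 on H3K27me3, and 6 were shorter than 1000 bp. The second, at chromosome 16, 12711887 to 12711935, was 49 bp long and lay on neither. Others on all 3 lists were chromosome 5, 108795972 to 108798604 (PCGF1 fold 6.63, RING1B fold 3.52), and chromosome 6, 30908255 to 30909811 (PCGF1 fold 6.51, RING1B fold 10.1). Very short peaks on all 3 lists were chromosome X, 113400788 to 113400852 (65 bp, RING1B fold 3.01), and chromosome 15, 47371555 to 47371675 (121 bp, RING1B fold 2.51). Their -log10 q was 16.1 and 17.3, on H3K27me3 regions of height 237 and 438, and high local background was not tested for them.

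The 10 RING1B peaks with the highest fold ranged from 14.2 to 25.7, and 6 of them held PCGF1 and 7 lay on H3K27me3. The highest, at chromosome 17, 4626056 to 4626689, was 634 bp long, held no PCGF1 peak and lay on the third tallest H3K27me3 region, of height 3323. High local background may account for such tall regions and cannot be told apart from binding here. The next were wide sites with several PCGF1 peaks: chromosome 10, 21867797 to 21880761 (RING1B fold 19.4, 3 PCGF1 peaks), and chromosome 2, 73103417 to 73120114 (RING1B fold 18.9, 5 PCGF1 peaks, the strongest of fold 6.38). Chromosome 15, 35219003 to 35237147 (fold 15.6), held 6 PCGF1 peaks and chromosome 4, 3834419 to 3868086 (fold 14.2), held 4. Strong RING1B sites with neither PCGF1 nor H3K27me3 were chromosome 9, 55053720 to 55054249 (fold 18.4), and chromosome 10, 119714600 to 119717204 (fold 18.3).

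The 10 tallest H3K27me3 regions had a median width of 3230 bp and heights from 1185 to 6010; 8 lay on RING1B and 3 on PCGF1. The highest PCGF1 folds on those 3 were 2.70, 1.93 and 4.98, against a median of 4.79 over the PCGF1 list. The tallest was at chromosome 9, 88445110 to 88448240, on a RING1B peak of fold 4.96 and without PCGF1. The next was chromosome 5, 114622870 to 114626500, with a height of 3552 and a RING1B peak of fold 5.57. The median height of the list was 68.5, and at the tallest regions high local background cannot be told apart from binding, as described in the closing section.

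**Figure D3:**
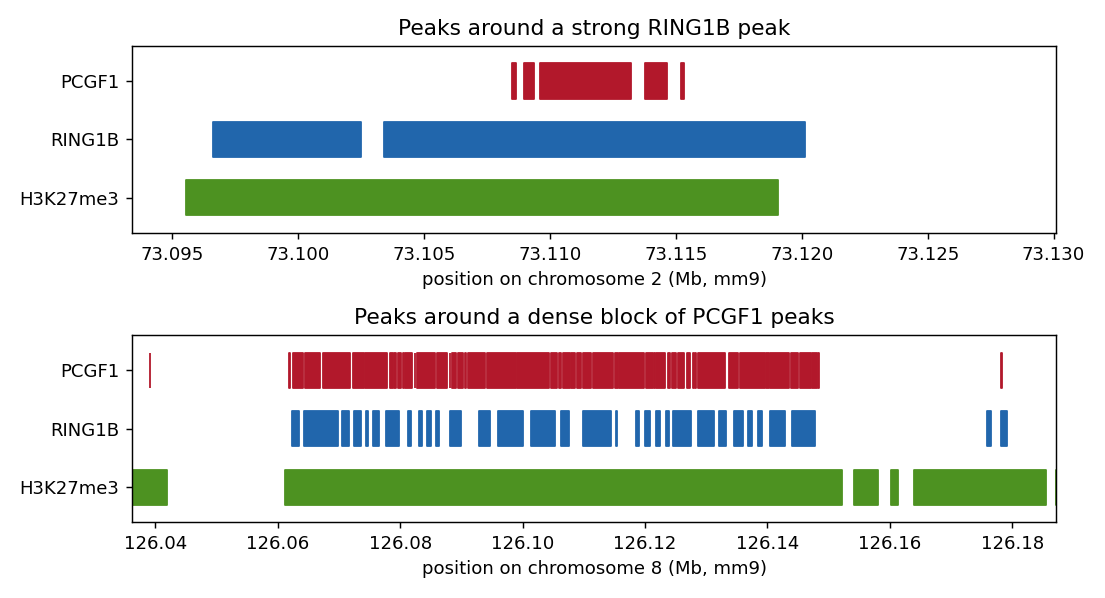
Intervals of the 3 lists along chromosome 2 around the RING1B peak of fold 18.9 (top) and along chromosome 8 around the region with the most PCGF1 peaks (bottom); x axes are mm9 positions in Mb, rows are the lists, and bars are drawn to scale. The RING1B peak on chromosome 2 holds 5 PCGF1 peaks within an H3K27me3 region, and the chromosome 8 region holds 48 PCGF1 and 30 RING1B peaks.

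PCGF1 was unevenly spread over chromosomes relative to RING1B. On chromosome 8, 12.7% (10.6 to 15.2) of 855 RING1B peaks held PCGF1, and on chromosome 19 9.12% (7.47 to 11) of 1074. On the other autosomes the share lay between 3.68% on chromosome 13 and 6.96% on chromosome 17, and on X it was 1.12% (0.452 to 2.30) of 624. A single H3K27me3 region on chromosome 8, 126061200 to 126152230, held 48 PCGF1 peaks, 24.5% of those on the chromosome, where the next highest region of the list held 10. It also held 30 RING1B peaks of median fold 3.09, so that all 3 lists were dense there, and its copy number was not analysed here. Its peaks are part of the counts above; without chromosome 8 the overlap of PCGF1 with RING1B was 34.4-fold over random placement. Without the peaks of that region, chosen after its values were seen, 9.58% of RING1B peaks on chromosome 8 held PCGF1, close to chromosome 19. The share of PCGF1 peaks on RING1B was 73.5% (66.7 to 79.5) on chromosome 8 and 75.6% (73.8 to 77.4) on the autosomes other than 8 and 19. X carried 0.506% of PCGF1 peaks, 2.50% of RING1B peaks and 10.0% of H3K27me3 regions, and made up 6.18% of the span.

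**Figure D4:**
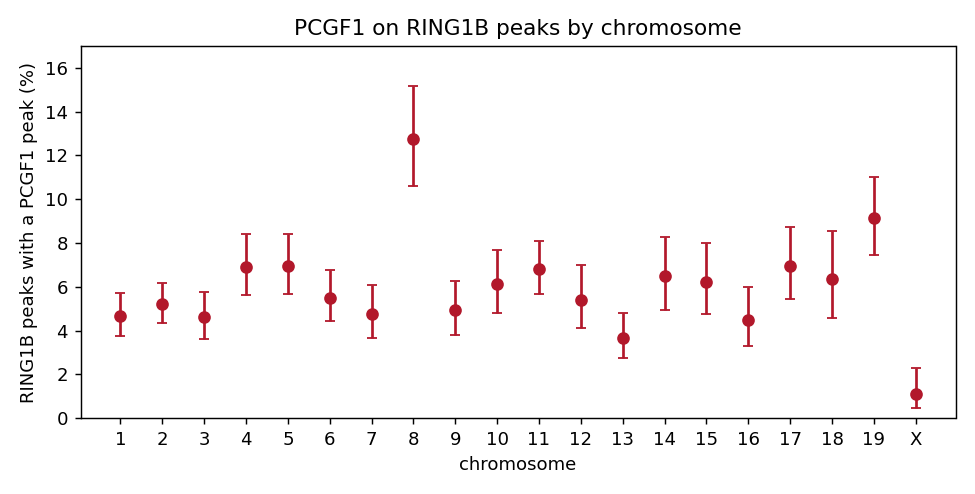
Percentage of RING1B peaks that hold a PCGF1 peak (y axis) on each chromosome (x axis), with exact 95% intervals as bars. Chromosome 8 stands at 12.7% and chromosome 19 at 9.12%, the other autosomes between 3.68% and 6.96%, and X at 1.12%.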

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

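Of 58 recomputed values, 51 kept their direction and their side of the threshold, 2 kept the direction and missed the threshold, and 5 turned. The settings chosen after seeing the data were the shift of 10 to 50 kb, leaving out chromosome 8, leaving out H3K27me3 regions of height 400 or more, and the taller 50% of H3K27me3 regions. The 3 overlaps stayed above random placement in every setting run: 10.8 to 47.6-fold for PCGF1 on RING1B, 1.35 to 3.59 for PCGF1 on H3K27me3 and 1.09 to 2.00 for RING1B on H3K27me3, each lowest against positions 10 to 50 kb away. The matched difference in H3K27me3 share between RING1B peaks with and without PCGF1, -4.68 points, turned to 1.69 points with 50% of the query peak covered, to 42.1 points with -log10 q of at least 5, where 14 RING1B peaks with PCGF1 were left, and to 13.2 points without width matching. It was -2.09 points and missed the threshold with the taller 50% of H3K27me3 regions. With -log10 q of at least 5, the excess in RING1B fold turned to -0.74 with PCGF1 and to 0.0065 with H3K27me3, and that in PCGF1 fold with H3K27me3 was 0.045 and missed the threshold, with 39 PCGF1 peaks left on H3K27me3. At that limit, RING1B peaks whose PCGF1 peaks fell below it were counted as without PCGF1. The setting without width matching leaves the difference in width in the value by construction; the cause of the other changes was not tested. The limit on -log10 q removed no H3K27me3 region, since every region of that list passed it. Promoter and gene list alternatives were not run, as no gene was assigned, and those per library (size factors, low counts, leaving out a replicate) were not run, as no values per library were used. No paired analysis was possible because each list stands for both of its libraries and carries no replicate number. Depth is unknown, so a PCGF1 peak missing from a RING1B site may lie below the detection limit, and at -log10 q of at least 5 the overlap rested on 64 PCGF1 peaks, of which 21.9% met a RING1B peak of the same limit, a ratio of 47.6. The RING1B peaks met had a median fold of 2.80, and high local background was not tested for them.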

Other observations

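Tests chosen after the result was seen were those with and without the dense block on chromosome 8, those against chromosome 19, the test of RING1B fold on X, the rank correlation given width, the distances from RING1B, and the reading of X coverage with chromosome 19 left out. The H3K27me3 regions that held Polycomb proteins were the large ones. Most regions, 127732 (94.3%), met neither RING1B nor PCGF1 and had a median width of 1750 bp and a median height of 67.4. Regions with RING1B alone numbered 6828, with medians of 5850 bp and 100, and regions with both RING1B and PCGF1 numbered 710, with medians of 15940 bp and 159.0. Another 121 regions held PCGF1 without RING1B, with medians of 10010 bp and 128.0. Wide regions have more room for peaks, and these classes were not matched on width. The region of chromosome 19, 44656030 to 44931190, was the widest of the 10 with the greatest total signal, at 275.2 kb, and held 6 RING1B and 3 PCGF1 peaks. The region of chromosome 15, 102746200 to 102980960, held 17 RING1B peaks and no PCGF1 peak, and that of chromosome 6, 52157530 to 52291840, held 13 RING1B and 5 PCGF1 peaks.

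Most RING1B peaks with PCGF1 held a single PCGF1 peak, 1123 of 1461 (76.9%), and 7 held 5 or more. The RING1B peak with the most was at chromosome 19, 45295215 to 45320033, with 9. For the 1830 PCGF1 peaks on a wider RING1B peak, the centre lay slightly farther from the RING1B centre than random positions did: the median distance was 0.412 of the distance from centre to edge, against 0.386 (0.367 to 0.405) at random (permutation of positions, two-sided p = 0.0080). PCGF1 peaks that reach past a RING1B edge were not set apart, which can raise the observed distance. Of the 634 PCGF1 peaks off RING1B, 286 (45.1%) lay within 1 kb of a RING1B peak and 377 (59.5%) within 10 kb, against 1.88% (0.960 to 3.04) and 12.6% (10.2 to 15.2) of random positions off RING1B (one-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). Across the 1461 RING1B peaks with PCGF1, Spearman's rho between the RING1B fold and the highest PCGF1 fold was 0.202; with the RING1B width held fixed by ranks it was 0.028, and rho between RING1B width and RING1B fold in these peaks was 0.70. These values are across peaks, which are not independent replicates.

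Chromosome 8 had 22.9 PCGF1 peaks per 100 RING1B peaks, against 16.9 on chromosome 19 and at most 13.0 on the other autosomes. It also had the fewest RING1B peaks per Mb of any autosome, 6.64, which raises this ratio. Its PCGF1 peaks per Mb, 1.52, were fewer than the 1.67 of chromosome 11 and the 3.12 of chromosome 19. A block near the end of chromosome 8, which may be a local copy number gain (not tested, since no input library was used), contributes: from 126061869 to 126148444, 48 PCGF1 peaks covered 83.4% of the sequence, the nearest PCGF1 peaks outside lay 22.7 and 29.7 kb away, and RING1B (30 peaks) and H3K27me3 (the greatest total signal of its list) were dense there too. Without the block chromosome 8 had 17.9 per 100 (15.0 to 21.4, from exact binomial limits), so the block does not account for the lead over the autosomes other than 19, but the lead over chromosome 19 was no longer detectable, at a ratio of 1.06 (exact conditional interval 0.830 to 1.35). RING1B peaks with PCGF1 on chromosome 8 were 2.44 times (exact Poisson interval 2.01 to 2.95) the number expected from their width and fold, and 1.84 times (1.45 to 2.29) without the block, against 1.51 on chromosome 19 and at most 1.22 on the other autosomes, which argues against wider or stronger RING1B peaks as the reason for the lead over the latter. A copy number gain of the whole chromosome in the cells used for the FLAG libraries may add to it and stays open: up to the chromosome's midpoint there were 14.4 (10.2 to 20) per 100, an interval that includes 13.0, and beyond it, without the block, 19.9 (16.0 to 24.5).

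X held 10.0% of H3K27me3 regions but 2.50% of RING1B and 0.506% of PCGF1 peaks. The values argue against weak calls near the threshold, since 9.25% (8.77 to 9.75) of the top 10% of regions by height lay on X, above its 6.18% of the span. Lower depth from a single copy would lower the height, but the median H3K27me3 height on X was not lower, at 72.3 (bootstrap interval 72.0 to 72.7, autosomes 66.2 to 71.9). This cannot exclude lower depth, since heights are known only for regions that passed the floor of 40. More of the mark on X would also raise them at any depth. For RING1B, lower depth stays open too: the median RING1B fold on X, 3.18 (3.16 to 3.22), was the lowest of any chromosome by less than its interval, next to 3.18 on chromosome 19, at 3.81 peaks per Mb. H3K27me3 regions covered 24.4% of X (22.1 to 26.5, resampling blocks of 1 Mb), below the 28.4% of chromosome 19 and next to the 23.6% of chromosome 11, the highest of the others, and their density was 82.8 per Mb on X against at most 65.8 on an autosome, that of chromosome 19. The covered share of X thus lay within the full autosomal range, which had been set beforehand as counting against broad H3K27me3 along an inactive X. That bound was decided by chromosome 19 alone, which also had the most RING1B peaks per Mb (18.4), so the explanation stays open. The regions on X were not unusually wide, with a median of 1890 bp, against 1710 to 2050 bp on the autosomes. The H3K27me3 list also held 35 regions on Y, and whether the cells had an inactive X was not tested.

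The tallest H3K27me3 regions were often shared with the other lists. Of the 100 tallest, 57 met RING1B and 26 met PCGF1, against 5.57% and 0.614% of all regions; their median width was 3645 bp, against 1840 bp for all regions and 6385 bp for regions with RING1B, and the shares were not matched on width. High local background, such as repeats collapsed in the assembly, may account for them and cannot be told apart from binding here. The 97 RING1B peaks on them had a -log10 q, for their fold, whose median stood at percentile 72.5 (bootstrap interval 61.2 to 88.2) of all RING1B peaks, where such background was set to exceed 95, but 30 of the 97 lay in the block on chromosome 8, and without these the percentile was 98.4 (80.3 to 99.3). No biological explanation was tested for these regions.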
